A study of Mus musculus with 19 samples.

How the data were processed

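RNA of single nuclei was counted in 17 mice and in a mouse fibroblast line by sNucDrop-Seq, a droplet method in which nuclei purified through a sucrose cushion are caught with barcoded beads so that each RNA molecule carries a nucleus barcode and a unique molecular identifier (UMI). The 19 samples fall into 5 groups by their labels: 1 library of whole NIH3T3 cells made by Drop-Seq, 1 library of NIH3T3 nuclei, 13 libraries of untreated cortex, 2 of saline-injected mice and 2 of mice injected with pentylenetetrazole (PTZ). The labels name each cortical library as a separate animal, so the spread between libraries of one group is a spread between animals.

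The deposited values are UMI counts per gene and barcode, whole numbers with exonic and intronic reads combined, per the names of the deposited tables. Reads had been aligned to mm10 with STAR 2.5.2a, per the submitters' processing notes. The gene annotation, the rule for collapsing UMIs and the use of strand in counting are not given in the sources used here. Each deposited table holds 2500 barcodes, and that of the 3T3 nuclei 3000. No value was negative or fractional. The barcode with the fewest genes had between 5 and 739 genes, depending on the cortical library, so some tables reach down to empty droplets.

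Barcodes with at least 800 genes and at most 10% mitochondrially encoded UMIs were kept. Of 42500 cortical barcodes, 21034 had 800 genes or more, and the mitochondrial limit removed 33 of these. Doublet scores were computed with scrublet in scanpy 1.11.5. Its automatic threshold marked between 0 and 2.15% of the barcodes of a library, so the 5% with the highest score in each library were removed instead, 1057 in all. This left 19944 nuclei. Shares of nuclei and sums of counts rest on these filters.

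Counts were scaled to 10000 per nucleus and log-transformed, and 2000 variable genes, 30 principal components, 20 neighbours and Leiden clustering at a resolution of 1 gave the clusters. No correction between libraries was applied. Of 43000 genes measured in the cortical libraries, 176 were kept out of the clustering: 150 activity, receptor and channel genes, and the mitochondrially encoded ones. Cell types are those of marker lists fixed before the data were examined, as were the gene lists, the tests, the rule for named genes and most of the alternatives. A marker counted as raised in a cluster at 0.25 or more of the highest level reached in any cluster, and a name needed at least 3 raised markers. A subtype name needed a mean marker position of at least 0.5 between lowest and highest cluster and a lead of 0.1 over the next subtype. These naming limits were set after the clusters were seen and before any PTZ result. Names below are shorthand for nuclei whose cluster is like that type by its markers. Clusters with markers of several classes were clustered again by themselves, and parts that stayed mixed were left unnamed.

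Cells are not replicates, so counts were summed per animal and class, and the sums were tested across animals. The main test was edgeR 4.0.16, quasi-likelihood with robust estimation, TMM normalization and its own expression filter, in R 4.3.3. P-values were adjusted by Benjamini-Hochberg, and 0.05 was the limit. PTZ was compared with saline in excitatory, inhibitory and medium spiny neurons and in neuron subtypes with at least 20 nuclei in each of the 4 animals. The difference of the PTZ responses of excitatory and inhibitory neurons was tested as an interaction over 8 sums, with the animal as a block. Excitatory and inhibitory neurons of the 13 untreated animals were compared over 26 sums, with the animal as a block, and only genes kept out of the clustering are read there. Class shares were compared by exact two-sided permutation tests. Values per gene are CPM, the usual scaling of counts to the library total, of the summed counts after TMM.

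The 16 gene lists were immediate-early transcription factors; early activity-induced signalling and synaptic effectors; late activity-response genes; glutamate receptor subunits; GABA receptor subunits; voltage-gated potassium channels; voltage-gated sodium and calcium channels; heat-shock and chaperone genes; inflammatory mediators; nuclear long non-coding RNAs; mitochondrially encoded genes; cytosolic ribosomal proteins; nuclear-encoded oxidative phosphorylation genes; fibroblast matrix and cytoskeleton genes; S-phase genes; and G2 and M-phase genes. Lists were tested with camera of limma 3.58.1 at the preset correlation of 0.01, with an estimated correlation and fry beside it. Adjustment covered the 43 tests over lists and classes.

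The genes named in the text follow a fixed rule. For excitatory and inhibitory neurons these are the 10 genes with the largest change in each direction among those past the limit, with both PTZ animals beyond both saline animals and a mean of at least 20 CPM, plus each member of the 3 activity lists that passed. The same rule with 5 genes per direction was used for medium spiny neurons. For the interaction they are the 10 genes with the smallest p, and for untreated cortex the 10 largest in each direction among genes past the limit with a mean of at least 20 CPM. For 3T3 they are the 10 largest ratios in each direction among genes with at least 200 UMIs, plus abundant members of each list. Genes named outside this rule, as members of a list with a small count or as background, were chosen after their values were seen. Positions are those of GENCODE vM21 on GRCm38, the assembly that mm10 names. Of 78 genes named for the cortex, 77 were matched there and 41 overlap another annotated gene, so their counts are uncertain to that extent.

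The 3T3 libraries, 1 per group, were described without a test. Shares of UMIs carry exact binomial intervals and gene values exact Poisson intervals at 95%, which cover counting error only. Each list's median was placed among 10000 random lists of the same size matched on expression. Where shares of nuclei with a UMI are given, each nucleus was also thinned to 1000 UMIs. Where a count is 0, the upper limit given is that of 3 counts.

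The edgeR tests of the neuron classes, the interaction and the untreated comparison were checked on simulated data. The subtype fits and the permutation tests were not. The data were built from the real means and library sizes. The simulated spread between animals was the average for genes of like expression, with no spread particular to a gene. Among genes with a mean of at least 20 CPM, 100 were changed by 2-fold and 100 by 4-fold. In the excitatory design 99 and 100 of them were recovered with 6 false among 205 calls over 14686 genes. In the inhibitory design 55 and 96 were recovered with 4 false among 155 over 9971 genes, and in the medium spiny design 40 and 89 with 1 false among 130 over 5775. The interaction design recovered 57 and 92 with 5 false among 154 over 13424 genes, and the untreated design 94 and 100 with 3 false among 197 over 11735. In the list test of excitatory neurons over 15041 genes, 1 changed list of 20 was recovered with 0 false calls. Its genes were simulated independently of each other. Lists with correlated members, and the list tests of the other classes, were therefore not checked. Over 80 pairs of libraries of one group no library was a copy of another, since the smallest chi-square per degree of freedom was 1.81 and at most 6 barcodes were shared.

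Alternatives covered DESeq2 1.42.0 size factors and its Wald test, the older quasi-likelihood fit of edgeR, no expression filter, the replicate number as a block, a fit over all 17 cortical animals, minimums of 500 and 1200 genes, no mitochondrial limit, doublets kept, clustering centred within libraries, and each saline or PTZ animal left out in turn. For 3T3 a minimum of 2000 genes, shares without mitochondrially encoded genes and thinned barcodes were tried as well. Restriction to named subtypes, an excitatory sample reduced to the number of inhibitory nuclei, and the untreated libraries split at a median of 2500 UMIs per nucleus were added after the data were seen. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used besides. All of the deposited tables were used.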

Results

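Nuclei of mouse cortex were profiled to ask which cell types make up the tissue and how neuronal activity changes their RNA. The 17 cortical libraries came from 13 untreated males of 6 to 10 weeks, 2 saline-injected males and 2 males injected with pentylenetetrazole (PTZ), a convulsant that blocks GABA-A receptors, at 50 mg/kg 1 h before the tissue was taken. The labels give cortex with striatum as the tissue of the 4 injected mice, while the protocol text speaks of cortex, and the age of these mice is 8 weeks in one place and 10 weeks in another. Library totals ran from 1794622 to 8350424 UMIs in untreated, 6437279 to 6765632 in saline and 5218221 to 5339751 in PTZ libraries. After filtering, 11018 untreated, 4729 saline and 4197 PTZ nuclei were left, between 176 and 2365 per animal. The median nucleus held 1447 to 5969 UMIs in untreated, 2143.5 to 2233 in saline and 1834 to 1939 in PTZ libraries. Whole cells and nuclei of NIH3T3, a mouse fibroblast line, were profiled in 1 library each, with 10126926 and 10849805 UMIs.

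Neurons dominated the untreated cortex. Excitatory neurons, named by markers such as the glutamate transporter Slc17a7, made up 77.4% ± 14.3 of nuclei per animal (SD, n = 13), with a range of 56.2 to 95.7%. Inhibitory neurons made up 9.24% ± 3.64. Astrocytes reached 2.30% ± 2.37, oligodendrocytes 1.98% ± 2.504, their precursors 0.936% ± 0.900, vascular cells 0.909% ± 1.39 and microglia 0.410% ± 0.487. These small shares moved with the settings by more than 1.5 times. With at least 1200 genes per nucleus astrocytes were 0.874%, oligodendrocytes 1.30%, vascular cells 0.392%, and precursors and microglia 0, while with at least 500 genes microglia were 0.928%. With clustering centred within libraries astrocytes were 0, oligodendrocytes 4.27% and vascular cells 0.423%, and precursors were 0.577% without the mitochondrial limit and 0.588% with doublets kept. No cluster was named newly formed oligodendrocyte, and 0 of 11018 nuclei allows the named class a share of up to 0.0272%. Names go to whole clusters, so such nuclei inside other clusters were not counted, and the limit does not bound the cell type. Nuclei left unnamed, most of them in clusters that joined markers of more than 1 class, made up 6.43% ± 6.42. They include a cluster with excitatory markers led by the myelin genes Mog, Mag and Mobp, which the oligodendrocyte share leaves out.

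The 13 animals split by depth, and nearly all glia came from the deeper libraries. In replicates 1 to 8, with medians of 3074.5 to 5969 UMIs per nucleus, excitatory neurons made up 67.05% ± 5.34, inhibitory neurons 11.5% ± 2.51, glia and vascular cells together 10.5% ± 4.22 and unnamed nuclei 10.4% ± 4.98 (SD, n = 8 animals). In replicates 9 to 13, with medians of 1447 to 2138.5 UMIs, the same shares were 94.0% ± 1.31, 5.63% ± 1.50, 0.189% ± 0.198 and 0.136% ± 0.139 (SD, n = 5 animals). No nucleus was named oligodendrocyte or microglia among the 5755 nuclei of these 5 animals, which allows each named class a share of up to 0.0521%. Some nuclei there stayed unnamed, so the limits do not bound the cell types as such. The pooled shares are therefore means over 2 kinds of library that the labels do not tell apart.

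**Figure D1:**
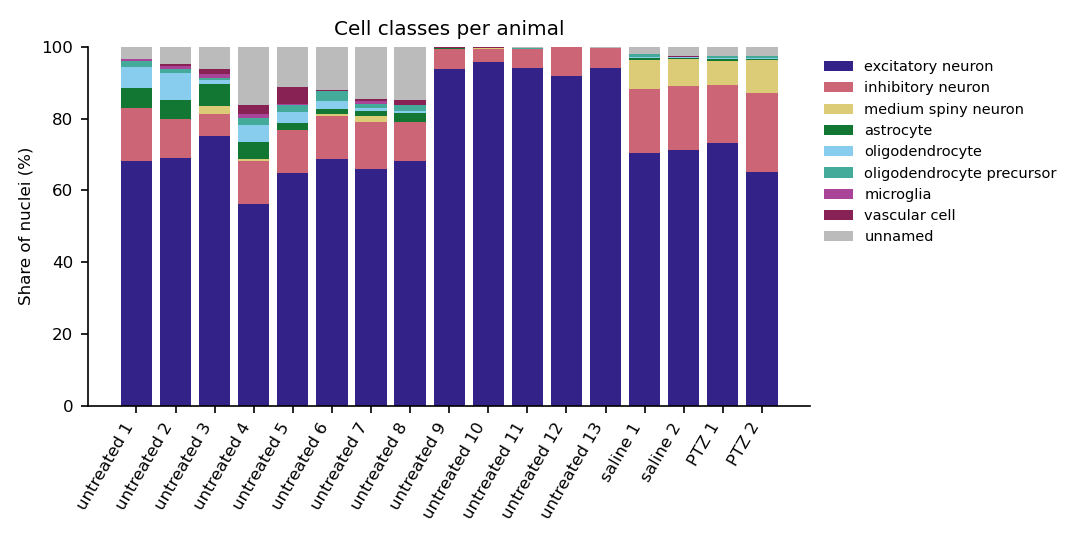
Share of nuclei in each cell class (percent, stacked bars, 1 bar per animal) in untreated, saline and PTZ animals. Untreated replicates 9 to 13 held 94.0% excitatory neurons on average, and medium spiny neurons averaged 7.90% in the 4 injected animals.

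Medium spiny neurons, the projection neurons of the striatum, were a check of the tissue label. They made up 7.90% ± 1.02 of nuclei in the 4 animals labelled cortex with striatum (6.84 to 9.26%) and 0.382% ± 0.705 in the 13 untreated animals, of which 7 held none and the highest held 2.29%. The difference of 7.52 percentage points was larger than the spread between animals (exact two-sided permutation p = 0.00042, the smallest that 2380 splits can give). Injection and tissue change together here, so the test compares the 2 sets of animals, and neither kind of untreated library holds an injected animal.

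No difference in cell class shares between PTZ and saline animals was detectable with 2 animals each. Excitatory neurons made up 70.9% ± 0.679 of saline and 69.1% ± 5.67 of PTZ nuclei, inhibitory neurons 17.7% ± 0.144 and 19.0% ± 4.08, medium spiny neurons 7.76% ± 0.327 and 8.05% ± 1.71, and glia with vascular cells 1.35% ± 0.598 and 1.26% ± 0.0746 (SD, n = 2 animals each). Unnamed nuclei made up 2.26% ± 0.389 and 2.4999% ± 0.0497. The microglial class held 0 nuclei in both groups, which under this naming allows a share of up to 0.0634% in saline and 0.0715% in PTZ animals. Another 40 nuclei led by Siglech and Csf1r stayed unnamed because they also carried markers of other classes, 27 of them from injected animals, so the limits do not bound microglia as such. The microglial share of PTZ minus saline animals was 0.253 percentage points with at least 500 genes per nucleus and 0.161 with doublets kept, where the animals of the groups did not overlap. Under the reported settings no class separated the groups (exact two-sided permutation p = 1 for all but oligodendrocytes, with 0.667, where the smallest p that 6 splits allow is 0.3333). The injected animals drew on other clusters than the untreated ones. A cluster led by Calb1 and Nectin3 held 1813 untreated and 36 injected nuclei, an excitatory cluster led by Abi3bp and Ndst4 held 94 and 853, and an inhibitory cluster led by Ecel1 and Baiap3 held 19 and 620. The last made up 1.96% of untreated inhibitory nuclei. Its share of inhibitory nuclei was 31.4% and 37.5% in the 2 saline animals, and 30.3% and 51.4% in the 2 PTZ animals. Ecel1 and Baiap3 are on none of the interneuron marker lists, so these nuclei are not shown to be cortical interneurons. They enter the inhibitory sums below, with an uneven share between the 2 PTZ animals.

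Excitatory and inhibitory neurons of untreated cortex were then compared in the activity, receptor and channel genes that had been kept out of the clustering. Inhibitory neurons held more Cacna2d2, an auxiliary calcium channel subunit, at 138 ± 49.3 against 14.1 ± 3.73 CPM in excitatory neurons (SD, n = 13 animals; log2 difference 3.29, SE 0.13, higher in 13 of 13, edgeR adjusted p = 9.56e-40). They also held more of the NMDA receptor subunit Grin3a (501 ± 146 against 54.6 ± 18.2 CPM; chromosome 4, 49661611 to 49845744 of mm10), the kainate receptor subunit Grik1 (1132 ± 388 against 137 ± 44.4) and Kcnc1 (373 against 57.2; chromosome 7, 46396497 to 46438704) and Kcnc2 (1774 against 338), potassium channels of fast-spiking cells. Scg2, Gria1, Grik2 and Gabrg3 were higher in inhibitory neurons by 1.31, 0.82, 0.73 and 0.66 on the log2 scale. Excitatory neurons held more of the plasticity genes Nrn1 (231 ± 34.3 against 43.0 ± 31.4 CPM), Arc (58.9 ± 26.3 against 12.9 ± 13.1) and Bdnf (80.5 ± 23.8 against 26.3 ± 25.7, higher in 12 of 13 animals, adjusted p = 0.000588), and of Kcnv1, Grm3, Nr4a2, Btg2, Pcsk1, Dusp6 and Grm8.

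By list, 14 of 17 immediate-early transcription factors, 12 of 21 early effectors and 9 of 16 late activity genes were higher in excitatory neurons, with 0, 0 and 5 higher in inhibitory neurons. Adjusted over the list alone these were 15, 13 and 10 against 0, 0 and 5. Of 23 glutamate receptor subunits 12 were higher in excitatory and 7 in inhibitory neurons (13 and 7 adjusted over the list alone), of 14 GABA receptor subunits 6 and 3 (7 and 3), of 21 potassium channels 12 and 6 (13 and 7), and of 23 sodium and calcium channels 17 and 2 (17 and 2). The list medians of the log2 difference, inhibitory minus excitatory, were -1.04, -0.90, -0.84, -0.40, -0.16, -0.52 and -0.45 in that order. In all, 23 of 135 genes were higher in inhibitory and 82 in excitatory neurons past an edgeR adjusted p of 0.05, from sums of 28547 to 4498620 UMIs over 16 to 1675 nuclei. Within the 8 deeper libraries 99 of 132 genes passed (23 and 76), all of them among the 105, and within the other 5 libraries 68 of 117 (14 and 54), of which 67 were among them.

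PTZ changed activity-regulated genes in excitatory neurons 1 h after the injection. Fosb and Fos, which encode AP-1 transcription factors, rose from 8.06 ± 0.244 to 30.8 ± 2.19 CPM (log2 fold change 1.93) and from 20.2 ± 2.41 to 43.7 ± 8.46 CPM (1.11, SE 0.18; SD, n = 2 animals per group). Atf3, Egr4 and Npas4, further activity-induced transcription factors, rose by 2.31, 1.19 and 0.74 on the log2 scale. Nptx2, a secreted pentraxin that gathers AMPA receptors at synapses (chromosome 5, 144545902 to 144557478 of mm10), rose from 35.6 ± 0.993 to 104 ± 2.95 CPM (1.55, SE 0.13), Ptgs2, the inducible cyclooxygenase, from 12.5 ± 2.07 to 40.1 ± 2.60 CPM, and the neurotrophin Bdnf from 73.4 ± 0.142 to 115 ± 17.2 CPM. Arc, which encodes a synaptic plasticity protein (chromosome 15, 74669083 to 74672570), fell from 38.8 ± 15.0 to 14.9 ± 5.28 CPM (-1.40, SE 0.26). The edgeR adjusted p-values were 1.32e-05 for Fosb, 0.000763 for Fos, 4.92e-07 for Nptx2, 1.43e-05 for Ptgs2, 0.00435 for Bdnf and 0.00317 for Arc.

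Of 19 immediate-early transcription factors tested in excitatory neurons 5 rose, and adjusted over the list alone 5 rose and Klf6 fell. Egr1 (100 to 126 CPM) and Nr4a1 (39.5 to 38.9 CPM) did not pass. Of 25 early effectors 8 rose, Rgs2, Ptgs2, Gadd45b, Arl4d, Ifrd1, Errfi1, Bdnf and Plk2, and 3 fell, the phosphatase Dusp1 (10.9 to 4.71 CPM), the pseudokinase Trib1 (21.4 to 6.24 CPM) and Arc. Adjusted over the list alone 11 rose and 3 fell, with Gadd45g, Pim1 and Dusp6 added, while Homer1 (498 to 457 CPM) did not pass. Of 16 late genes 5 rose, Nptx2, Grasp, Nrn1, Mapk4 and Fbxo33, and Pcsk1, a prohormone convertase, fell from 83.8 to 52.9 CPM. Adjusted over the list alone 9 rose and 1 fell. Grin1, the obligatory NMDA receptor subunit, rose from 485 to 727 CPM as 1 of 24 glutamate receptor subunits, and Gabra4 from 134 to 189 CPM as 1 of 14 GABA receptor subunits, with 2 higher (Gabra4 and Gabra5) and 1 lower (Gabrd) adjusted over the list alone. Tpm1 rose as 1 of 10 fibroblast genes and Cenpa as 1 of 9 G2 and M-phase genes. DESeq2 called 3 of the immediate-early, 7 of the early and 5 of the late genes, without Atf3, Npas4, Arl4d, Plk2, Dusp1, Trib1 and Fbxo33, and it did not call Gabra4 or Cenpa. In the other 9 lists none of 239 genes passed by edgeR or DESeq2, with 16 at an unadjusted p under 0.05 (21 potassium channels, 23 sodium and calcium channels, 9 heat-shock genes, 3 inflammatory mediators, 11 nuclear long non-coding RNAs, 9 mitochondrially encoded genes, 79 cytosolic ribosomal proteins, 71 oxidative phosphorylation genes and 13 S-phase genes).

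The largest changes outside the lists in excitatory neurons, among genes with a mean of at least 20 CPM, were those of Mir670hg, Strip2, Lsm11, Lonrf3, Snx1, Wipf3 and Fkbp5, which rose by 2.20, 1.84, 1.46, 1.43, 1.33, 1.32 and 1.23 on the log2 scale. Mir670hg, a long non-coding RNA that holds the microRNA genes Mir670 and Mir129-2 (chromosome 2, 94160636 to 94264918), rose from 88.6 ± 3.78 to 407 ± 31.0 CPM (adjusted p = 7.05e-10). Tnfrsf25, a death receptor, fell from 31.5 ± 1.78 to 8.79 ± 0.499 CPM (-1.84), Prrt1 from 52.6 to 22.4 CPM and Map6, which stabilizes microtubules, from 154 to 74.9 CPM. Cbfa2t3, Rabif, Cfp, Spink10, Gm12940 and Gm12353 fell by 1.07 to 1.22 on the log2 scale. In all 421 of 15041 genes rose and 333 fell past an edgeR adjusted p of 0.05, of which 83 and 71 changed by 2-fold or more. The sums held 2990480 to 4533010 UMIs, and the median log2 fold change of all genes was 0.00. DESeq2 called 231 genes, a fit over all 17 animals 1 (Strip2), a fit without the expression filter 1 (Mir670hg), nuclei with at least 1200 genes 446 and a sample of nuclei of the size of the inhibitory class 309. Without saline replicate 1 the count was 157 and Arc (-0.93), Arl4d, Atf3, Bdnf, Dusp1, Errfi1, Fbxo33, Mapk4, Npas4, Nrn1, Pcsk1 and Plk2 no longer passed. Without saline replicate 2 it was 296 and 5 of these did not pass. Without PTZ replicate 1 it was 1515 (752 higher and 763 lower), and without PTZ replicate 2 it was 1516 (965 and 551) with Arl4d and Atf3 lost.

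**Figure D2:**
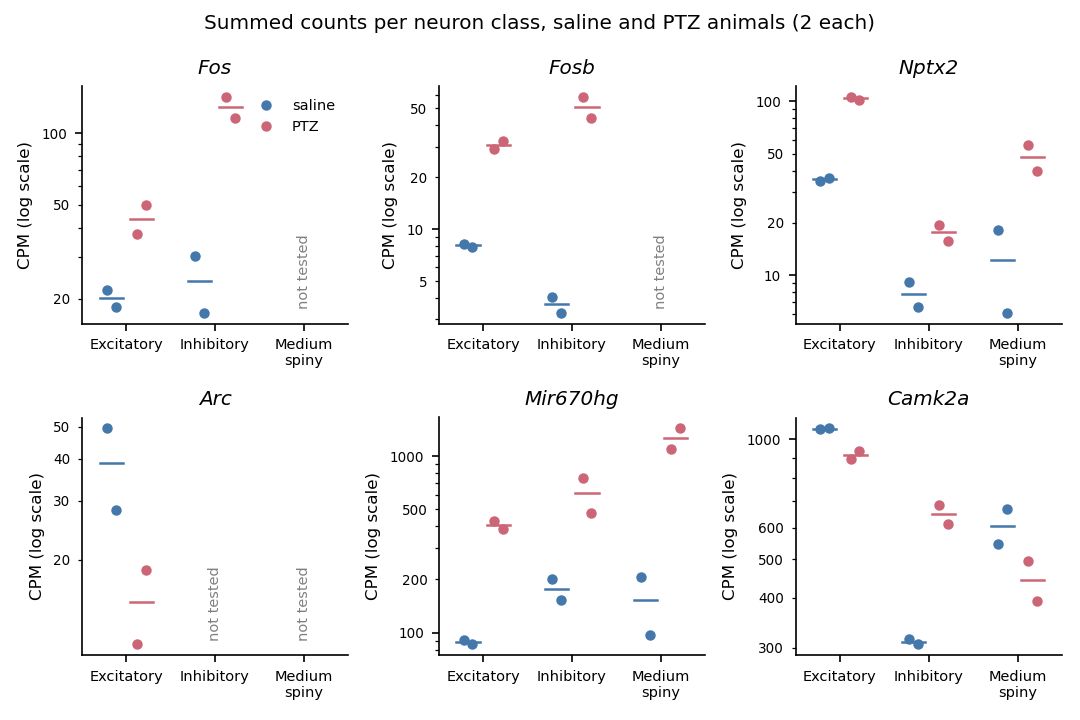
CPM (log scale) of 6 genes in summed excitatory, inhibitory and medium spiny neurons, with 1 point per animal and a line at the mean of the 2 saline or 2 PTZ animals. Fos in inhibitory neurons averaged 23.9 in saline and 129 in PTZ animals, and Arc in excitatory neurons 38.8 and 14.9.

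In inhibitory neurons PTZ raised the same AP-1 genes. Fosb rose from 3.67 ± 0.542 to 51.1 ± 10.2 CPM (log2 fold change 3.77, SE 0.44, edgeR adjusted p = 1.98e-05; chromosome 7, 19302696 to 19310051 of mm10) and Fos from 23.9 ± 9.09 to 129 ± 18.9 CPM (2.41, SE 0.25, adjusted p = 6.89e-06; chromosome 12, 85473890 to 85477273; SD, n = 2 animals per group). Egr1, a zinc-finger transcription factor, rose from 40.5 ± 1.48 to 98.3 ± 10.0 CPM. Outside the lists Mir670hg (177 ± 33.4 to 616 ± 194 CPM), the transcription factor Klf13 (25.6 to 79.7), the nuclear lamina gene Lmna (17.8 to 52.3), the splicing factor Srsf10 (98.6 to 184) and Camk2a, a kinase of excitatory synapses (311 ± 6.71 to 650 ± 50.1 CPM, 1.06, SE 0.16, adjusted p = 0.00173), rose. Slirp, which binds mitochondrial RNA, fell from 122 to 45.7 CPM and Gm4258 from 220 to 114 CPM. Camk2a is one of the markers used to name excitatory neurons, and Slc17a7, another of them, stood at 12.0 CPM in saline and 21.2 CPM in PTZ inhibitory nuclei.

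The list counts in inhibitory neurons were 3 of 13 immediate-early transcription factors that rose (6 adjusted over the list alone, with Egr4, Junb and Npas4), 0 of 11 early effectors (4 adjusted over the list alone, Rgs2, Gadd45b, Homer1 and Plk2) and 0 of 14 late genes (2, Penk and Grasp). Over the 15 lists without a call, none of 252 genes passed by edgeR or DESeq2, with 21 at an unadjusted p under 0.05 and 6 past when adjusted over the list alone. In all 8 of 10283 genes rose and 2 fell in edgeR, from sums of 641885 to 991122 UMIs, with 986 genes at an unadjusted p under 0.05. DESeq2 called 4 genes (Fosb, Fos, Mir670hg and Camk2a), the older edgeR fit 16, no expression filter 2 (Fosb and Fos), a fit over all 17 animals 3 (Fosb, Fos and Mir670hg), doublets kept 41 (23 higher and 18 lower) and named subtypes 29 (18 and 11). Without saline replicate 1 the count was 4, without saline replicate 2 it was 5, without PTZ replicate 1 it was 111 (40 higher and 71 lower) and without PTZ replicate 2 it was 88 (65 and 23). Of the 10 genes only Fos and Fosb passed in each of these 4 fits. Lmna, Egr1, Camk2a, Srsf10, Slirp and Gm4258 were lost without saline replicate 1, and these with Klf13 and Mir670hg without saline replicate 2.

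Single nuclei gave the same order of groups for Fos in 2 classes, where it was seen in 4.77% of saline and 17.0% of PTZ inhibitory nuclei, and in 4.803% and 8.57% of excitatory nuclei. In medium spiny neurons the means were 1.62% and 1.75%, from 2 to 4 nuclei per animal. The groups overlapped there, with 2.12% and 1.12% in the saline and 1.32% and 2.17% in the PTZ animals. With each nucleus thinned to 1000 UMIs and 0 nuclei left out, the means of inhibitory, excitatory and medium spiny neurons were 1.91% and 10.2%, 2.09% and 4.18%, and 0.794% and 0.875%. Bdnf, which medium spiny neurons make little of, was seen in 0.562% and 0.875% of them as a background level, against 12.5% and 17.7% of excitatory nuclei (5.66% and 9.48% thinned). Mir670hg was seen in 12.6% and 41.2% of excitatory nuclei (6.02% and 26.2% thinned) and in 15.2% and 64.6% of medium spiny neurons (10.3% and 51.9% thinned). Median UMIs per nucleus were 2248.5 to 2372.5 in saline and 1904.5 to 2033 in PTZ animals for excitatory, 1964 to 2029 and 1599 to 1779 for inhibitory, and 1793 to 1858 and 1652 to 1732.5 for medium spiny neurons.

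In medium spiny neurons the smallest p was that of Mir670hg, which rose from 152 ± 77.4 to 1270 ± 237 CPM (SD, n = 2 animals per group; log2 fold change 3.04, SE 0.21, edgeR adjusted p = 2.43e-16). Fdft1, which makes squalene in the cholesterol pathway, rose from 10.7 to 71.6 CPM, and Gm44529, Ippk and Pabpc4 by 2.22, 2.14 and 2.01 on the log2 scale. N4bp2l1 fell from 128 to 29.3 CPM, Kitl, the ligand of the receptor Kit, from 133 to 48.2 CPM, and Zmat3 and Hectd2 by 1.59 each on the log2 scale. St8sia4, a polysialyltransferase, was down to 2 UMIs in PTZ against 28 in saline animals, a saline to PTZ ratio of 11.3 (exact 95% counting interval 2.86 to 98.2). Grin1 rose from 532 to 816 CPM as 1 of 21 glutamate receptor subunits and mt-Nd5 from 63.5 to 145 CPM as 1 of 7 mitochondrially encoded genes, and DESeq2 called neither. None of 7 immediate-early transcription factors, 5 early effectors or 12 late genes passed over all genes, and Egr1 was at 128 and 125 CPM. Adjusted over the list alone Rgs2 (190 to 279 CPM) and Nptx2 (12.2 to 47.9 CPM) were higher. Over the 11 lists without a call, none of 167 genes passed by edgeR or DESeq2, with 13 at an unadjusted p under 0.05.

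In all 36 of 6119 genes rose and 20 fell in medium spiny neurons, from sums of 261600 to 375397 UMIs. DESeq2 called 6 genes, no expression filter 5, a fit over all 17 animals 1 (Mir670hg), nuclei with at least 500 genes 91 and with at least 1200 genes 9. The count was 12 without saline replicate 1 (5 higher and 7 lower), 17 without saline replicate 2 (10 and 7), 89 without PTZ replicate 1 (45 and 44) and 39 without PTZ replicate 2 (28 and 11). Of the 10 named genes DESeq2 called Mir670hg alone, and Mir670hg and N4bp2l1 passed in each of these, and 6, 6, 6 and 5 of the others were lost.

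Whether excitatory and inhibitory neurons responded differently to PTZ was tested as an interaction. Camk2a had the smallest p: it rose in inhibitory neurons, while excitatory neurons held 1132 and 1135 CPM in the saline and 955 and 986 CPM in the PTZ animals (difference of the log2 fold changes 1.28, SE 0.11, edgeR adjusted p = 2.15e-08; chromosome 18, 60925618 to 60988152 of mm10). The response of Cpeb3, a translational regulator at synapses, was higher in excitatory neurons (372 and 344 to 613 and 523 CPM) than in inhibitory neurons (383 and 350 to 370 and 286 CPM), with a difference of -0.84. Mef2c, an activity-regulated transcription factor, Apba1, Pparg, Khdrbs3, Wipf3, Amph, Mkx and Neb differed in the same direction as Cpeb3, by -0.73, -0.76, -1.58, -0.90, -0.90, -0.68, -0.92 and -2.33. In all 25 of 13764 genes passed, 6 with a higher response in inhibitory and 19 in excitatory neurons. A response here is the log2 fold change with its sign, so a higher one can come from a decrease in the other class. Mef2c was at 0.23 in excitatory and -0.51 in inhibitory neurons, and Dlg4 at -0.96 and -0.02.

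Of 18 immediate-early transcription factors 0 differed over all genes in the interaction by edgeR, with 4 at an unadjusted p under 0.05, and adjusted over the list alone 4 did, each with a higher response in inhibitory neurons (Klf10 by 2.00, Fosb by 1.84, Fos by 1.30 and Egr1 by 0.92). Of 24 early effectors Trib1 differed over all genes (2.79), and adjusted over the list alone Trib1, Sik1 (2.58) and Homer1 (0.71) did, in the same direction. Trib1 was low in inhibitory neurons, at 4.65 and 6.07 CPM in the saline and 13.5 and 8.25 CPM in the PTZ animals. It fell under the expression filter in the test of that class, and its log2 fold change in excitatory neurons was -1.77. Of 16 late genes 0 differed, with 2 at an unadjusted p under 0.05. Adjusted over the list alone, 2 of 14 GABA receptor subunits, 2 of 21 potassium channels and 1 of 9 heat-shock genes had a higher response in excitatory neurons. DESeq2 called 1 gene in all, Camk2a, and no member of these lists. The 25 calls were 1 without the expression filter, 1 without the animal as a block, 56 from nuclei with at least 500 genes, 2 from those with at least 1200 and 60 with doublets kept. With only nuclei of the named subtypes there were 34 (14 with a higher response in inhibitory and 20 in excitatory neurons), of which 15 were among the 25. They were 10 without saline replicate 1, 13 without saline replicate 2, 4 without PTZ replicate 1 and 53 without PTZ replicate 2. Of the 10 named genes Camk2a and Cpeb3 passed in all 4 fits, with 4, 3, 8 and 0 lost.

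As whole lists, the 3 activity lists were higher after PTZ in excitatory and inhibitory neurons by camera at the preset correlation, and these calls were lost with an estimated correlation (adjusted p = 0.645 to 0.799). The mean log2 fold change of the immediate-early list was 0.42 in excitatory (adjusted p = 0.00239) and 1.02 in inhibitory neurons (adjusted p = 1.98e-07), that of the early effectors 0.23 and 0.34 (adjusted p = 0.00308 and 0.0175), and that of the late genes 0.39 and 0.52 (adjusted p = 2.23e-05 and 0.000266). Each list was cut to the genes past the filter of the class, 19 and 13 for the immediate-early list, so the means of the classes are not over the same genes. The filter can favour genes high in PTZ animals, as with Fosb (7 saline and 75 PTZ counts in inhibitory neurons), so means and p-values can lean toward higher. The mitochondrially encoded list was higher in medium spiny neurons (mean 0.40, adjusted p = 0.0483, and adjusted p = 0.799 with an estimated correlation), and without PTZ replicate 1 its test pointed to lower (p = 0.206) at a mean of 0.09. With an estimated correlation the 3 activity lists had adjusted p = 0.799, 0.799 and 0.645 in excitatory neurons and adjusted p = 0.645, 0.799 and 0.645 in inhibitory neurons. Of the 43 tests 12 had an unadjusted p under 0.05, and fry called 0 lists in one direction. Without PTZ replicate 1 there were 10 calls and without PTZ replicate 2 there were 16. On the log CPM values that camera uses, mean, median and test differed in sign for the early effectors (mean 0.04, median 0.12, test lower) and potassium channels (mean -0.05, median 0.05, test higher) of medium spiny neurons. They also did for the potassium channels (mean -0.00, median -0.02, test higher) and inflammatory mediators (mean 0.06, median -0.01) of excitatory neurons, and the glutamate receptors (mean 0.04, median -0.01), heat-shock genes (mean -0.04, median 0.05) and fibroblast genes (mean -0.03, test higher) of inhibitory neurons. The medians of the edgeR fold changes were 0.03 for the inflammatory mediators of excitatory and 0.03 for the glutamate receptors of inhibitory neurons.

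Within neuron subtypes, Fos rose in Sst interneurons from 18.2 to 309 CPM (log2 fold change 4.01, edgeR adjusted p = 1.75e-05), in Pvalb interneurons from 14.9 to 102 CPM (2.78) and in Lamp5 or Ndnf interneurons from 13.9 to 467 CPM (5.11). In Vip interneurons Fos was at 60.7 and 89.0 CPM and fell under the expression filter. Among excitatory subtypes Fos rose in layer 6 (18.1 to 60.7 CPM) and upper-layer neurons (20.4 to 36.9 CPM), and Nptx2 rose in both, by 1.30 and 2.11 on the log2 scale. Mir670hg passed in 9 of the 10 subtypes, and in Vip interneurons its log2 fold change was 0.55 (adjusted p = 0.85). Arc fell in layer 6 (-2.49, adjusted p = 3.65e-05), claustrum-like (-3.25, adjusted p = 0.00386) and layer 4 neurons (-1.82, adjusted p = 0.0105), and its log2 fold change was -1.58 in layer 5 (adjusted p = 0.25) and -0.30 in the upper layer (adjusted p = 0.672).

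Upper-layer neurons, with 431 to 590 nuclei per animal, had the most calls of the 10 subtypes, 569 higher and 317 lower of 11039 genes. Layer 6 had 98 and 63, claustrum-like neurons 54 and 31, layer 4 34 and 20, layer 5 4 and 10, layer 6b 4 and 0, Sst 7 and 1, Pvalb 6 and 1, and Lamp5 or Ndnf 3 and 0. Vip interneurons, with 31 to 54 nuclei per animal, had 0 calls by edgeR, with 132 of 2292 genes at an unadjusted p under 0.05. The median log2 fold change of the immediate-early list, over 10 to 17 genes, was 0.59 in upper-layer, 0.23 in claustrum-like, 0.18 in layer 6, 0.07 in layer 5 and -0.24 in layer 4 neurons. In Sst and Pvalb interneurons it was 4.01 and 2.20 over 3 genes each, a set that the expression filter can favour toward genes high in PTZ animals, so their sign is not read as a result. Upper-layer neurons had the highest and layer 4 neurons the lowest of the 5 excitatory medians whichever animal was left out, with 0.74 and 0.54 in the upper layer without saline replicates 1 and 2, and 0.83 and 0.48 without PTZ replicates 1 and 2. The other medians changed places. Without saline replicate 1 the medians were 0.18 in layer 4, 0.45 in layer 5, 0.53 in layer 6 and 0.50 in claustrum-like neurons. Without saline replicate 2 they were -0.53 in layer 4, -0.00 in layer 5 and 0.07 in layer 6. Without PTZ replicate 1 they were -0.03 in layer 4 and 0.56 in claustrum-like neurons, and without PTZ replicate 2 0.11 in layer 5 and 0.36 in claustrum-like neurons. Inhibitory nuclei without a subtype made up 34.2% and 40.4% of saline and 33.9% and 53.4% of PTZ inhibitory nuclei, and excitatory ones 7.56% and 7.70%, and 5.88% and 8.57%. Some nuclei of the excitatory clusters led by Zbtb20, described under other observations, carry one of these excitatory subtype names. Subtypes were not compared with each other by a test.

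The 3T3 libraries ask what a nucleus keeps of a cell's RNA. With 1 library each there are no replicates, and the intervals cover counting error only. The cells were prepared by Drop-Seq and the nuclei by sNucDrop-Seq through a sucrose cushion. The ratios below therefore cannot tell the nucleus apart from the preparation or the library. The 1159 cells held a median of 6488 UMIs and 3204 genes and the 1986 nuclei 4198 UMIs and 2482 genes, and thinned to 1000 UMIs they held 783 and 797.5 genes (2 nuclei left out). Nuclear long non-coding RNAs took 2.43% of nuclear and 1.30% of cellular UMIs, a ratio of 1.86 (exact 95% interval 1.85 to 1.88). Malat1, a nuclear-retained RNA, was at a ratio of 2.40 (2.39 to 2.42), while 4 of 8 list members were higher in nuclei, Gas5 was at 0.796, and the list's median log2 ratio of 0.11 lay at percentile 61.6 of random lists. Cytosolic ribosomal proteins took 3.46% of nuclear and 5.88% of cellular UMIs (ratio 0.588, 76 of 86 genes lower) and oxidative phosphorylation genes 1.56% and 2.42% (0.644, 70 of 73 lower), both at percentile 0. Mitochondrially encoded genes took 2.65% and 1.92% (1.38), but 5 of 17 genes were higher and the median log2 ratio was -0.53, at percentile 0. The ribosomal RNA mt-Rnr2 was at 2.87, while mt-Cytb and mt-Nd2 were at 0.691 and 0.395.

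G2 and M-phase genes took 0.299% of nuclear and 0.217% of cellular 3T3 UMIs (ratio 1.38, 19 of 22 higher, percentile 98.9), with Cenpe at 1.82 and Top2a at 1.39. Fibroblast genes were at 0.837 (Col1a2 1.45, Lgals1 0.638), heat-shock genes at 0.885, S-phase genes at 0.944 and immediate-early transcription factors at 0.935. The median log2 ratios of these lists lay at percentiles 5.12, 25.9, 0.49 and 0.92 of random lists, in that order. The S-phase ratio was 1.08 after thinning. The 10 highest nuclear ratios were those of Hist1h1b, a linker histone gene, at 11.9 (8.76 to 16.6), Hist1h2ae (7.87), Hist1h1d (7.53), AY036118 (7.38), Gm42418 (5.09), Hist1h1e (4.78), RP23-165H7.3 (4.07), Kcp (3.90), Gm20417 (3.70) and Dach1 (3.56). AY036118 and Gm42418 lie in ribosomal RNA-like sequence, so their counts are uncertain. On the cellular side the cell to nucleus ratio was 2.86 (2.82 to 2.91) for Fth1, the ferritin heavy chain, 2.59 for Atp5e, 2.53 for mt-Nd2, 2.46 for Toporsos, 2.31 for Rps20, 2.19 for Mrpl30, 2.18 for Gm13056 and 2.16 for 2010107E04Rik. It was 3.76 and 2.19 for Gm28438 and Gm10420, which are annotated as pseudogenes. Whether reads of their parent genes add to these counts was not tested. Of 10343 genes with at least 200 UMIs, 327 were at least 2-fold higher in nuclei and 32 in cells. With the genes in 5 equal groups by span, the median log2 ratio went from -0.15 for the shortest genes through -0.08, 0.05 and 0.20 to 0.47 for the longest (Spearman's rho across genes 0.509, genes not being independent replicates).

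**Figure D3:**
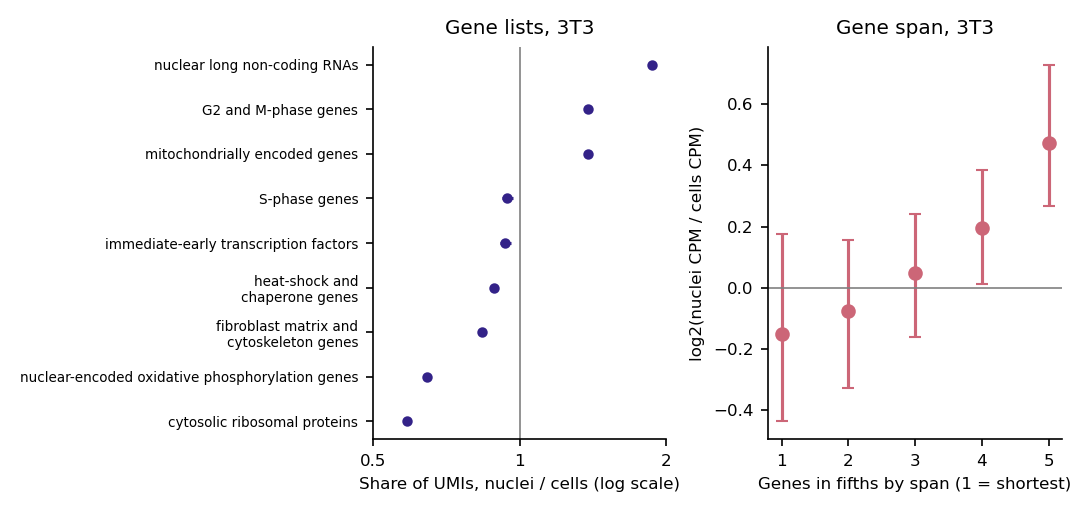
Left, the nucleus to cell ratio of the share of 3T3 UMIs (log scale) for 9 gene lists, with exact 95% intervals; right, the median log2 ratio of nuclear to cellular CPM in 5 equal groups of genes by span, with quartiles. The list ratios ran from 0.588 for cytosolic ribosomal proteins to 1.86 for nuclear long non-coding RNAs.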

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

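Both tests of Camk2a were chosen before their results were seen, and the pattern itself was found in the same data. The PTZ responses of excitatory and inhibitory neurons differed for 25 genes in a test of the difference itself, which singled out each result in these paragraphs. For Camk2a the difference of the log2 fold changes, inhibitory minus excitatory, was 1.28. It was -0.84 for Cpeb3, -0.73 for Mef2c, -0.76 for Apba1, -1.58 for Pparg and -0.90 for Khdrbs3. It was -0.90 for Wipf3, -0.68 for Amph, -0.92 for Mkx and -2.33 for Neb. Without PTZ replicate 1 the 25 genes became 4, and of the 10 named genes Camk2a and Cpeb3 passed in each fit that left out 1 animal.

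Camk2a rose in inhibitory nuclei of the PTZ animals. RNA or doublets from excitatory neurons may raise it, since Camk2a is abundant there, but 42 genes that excitatory neurons hold at 4 times the inhibitory level or more had a median log2 fold change of 0.54 in inhibitory nuclei (quartiles 0.28 and 0.74), below the 1.63 that the Camk2a rise would need. A different mix of inhibitory subtypes would leave Camk2a level within them, but in 4 of 4 named interneuron subtypes both PTZ animals lay above both saline animals, as in Sst (296 to 998 CPM) and Pvalb interneurons (226 to 806 CPM). The positive median of the excitatory genes leaves open that such RNA adds a part of the rise. A response of interneurons to PTZ is the biological hypothesis, which these 4 animals raise and cannot settle, and without saline replicate 1 or 2 the rise in inhibitory neurons alone was 1.08 and 1.04 and no longer passed.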

How the results depend on the processing

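The swaps of class names, the split of untreated libraries by depth, named subtypes and the sample of excitatory nuclei were chosen after the data were seen. Fits that leave out 1 saline or PTZ animal assume that the lone animal left varies like the other group. Of the results that answer a comparison, 59 values under an alternative stayed close to the reported one (counts within 1.5 times, other values within their spread) and 49 moved further. Of the other results 1220 stayed the same, 269 lost the threshold, 40 moved and 2 reversed.

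In excitatory neurons 754 genes changed with PTZ. The count was 231 with the DESeq2 Wald test (70.6% of them higher, against 55.8%), 1 without the expression filter, 1 in the fit over all cortical animals, 446 with at least 1200 genes per nucleus, 309 with as many nuclei as the inhibitory class, and 157 to 1516 with 1 animal left out. In inhibitory neurons the 10 became 4 with DESeq2, 16 with the older edgeR fit, 2 without the filter, 3 over all cortical animals, 41 with doublets kept, 29 in named subtypes and 4 to 111 with 1 animal left out. In medium spiny neurons the 56 became 6 with DESeq2, 5 without the filter, 1 over all cortical animals, 91 and 9 with at least 500 and 1200 genes, and 12 to 89 with 1 animal left out. The 25 genes of the interaction became 1 with DESeq2, 1 without the filter, 1 without the animal as a replicate block, 56 and 2 with at least 500 and 1200 genes, 60 with doublets kept and 4 to 53 with 1 animal left out. Of the 7 gene list calls 0 were left with an estimated correlation and 0 with fry, and there were 8 to 16 with 1 animal left out. The fits over all cortical animals and without the filter take in libraries of another depth and tissue or genes near 0. Those with fewer nuclei or animals hold fewer counts. Fewer counts would not raise the number of calls, as leaving out a PTZ animal did in excitatory and inhibitory neurons. The 2 saline libraries differed by a chi-square per degree of freedom of 1.81 and the 2 PTZ libraries by 5.43. Beyond that the cause was not tested.

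Whether the replicate numbers pair the saline and PTZ animals cannot be settled with 2 animals per group. The correlations of their deviations were 0.108, 0.0466 and -0.0142 in excitatory, inhibitory and medium spiny neurons. With the replicate block the counts were 1220, 60 and 31 in place of 754, 10 and 56, the 60 being 29 higher and 31 lower. There were 7 gene list calls with it as without it, and 6 subtypes with a positive immediate-early median, 2 of them over 3 genes each.

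In untreated cortex the 105 genes became 68 within the 5 libraries under a median of 2500 UMIs, where the excitatory share of 77.4% became 94.0%, and the cause was not tested. Of 40 arrangements of the class names within animals, 1, the real one, gave 105 genes, and the highest of the others gave 0. A swap mixes 2 classes that the clustering had set apart by expression, so low counts were bound to follow. The swaps therefore cannot decide whether chance plays a part. The striatal share differed by 5.88 to 8.26 percentage points under the alternatives, at the smallest exact p each time. In 3T3 the long non-coding ratio of 1.86 became 1.88, 1.84 and 1.79 with at least 500, 1200 and 2000 genes, and 1.88 without mitochondrially encoded genes, and the cause was not tested. Of the reversed results, the ratio of S-phase genes became 1.08 with thinned barcodes, and in PTZ against saline, gene lists: mitochondrially encoded genes, medium spiny, the test pointed to lower without PTZ replicate 1, at a mean log2 fold change of 0.0859, which ranged up to 0.762 with another animal left out. The cause was not tested for either. The medium spiny and inhibitory sums held 261600 to 375397 and 641885 to 991122 UMIs, against 2990480 to 4533010 in excitatory neurons. In simulated data of these sizes 40, 55 and 99 of 100 genes changed by 2-fold were recovered. The changed genes had a mean of at least 20 CPM, so the recovery of rarer genes was not checked.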

Other observations

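The depth and subtype tests of Arc and the tests of shed RNA and of overlapping genes for Mir670hg were chosen after the results they bear on had been seen, and the injection test of Arc and the neighbour test of Mir670hg before. Small groups of inhibitory nuclei outside the named interneuron subtypes were led by genes that are not on the marker lists of those subtypes. A group of 22 nuclei was led by Chat and Slc5a7, which make and recycle acetylcholine, with Isl1 and Lhx8. Another 22, of which 81.8% came from 1 library, were led by Eomes, Cdhr1 and Tbx21, genes of mitral and tufted cells. Those cells are glutamatergic, so the inhibitory class name is in doubt for this group. Groups of 65 and 57 nuclei were led by Prkcd and Zic1 and by Meis2 and Pbx3. Among excitatory nuclei, clusters of 518 and 152 nuclei were led by genes that include Zbtb20, the latter also by Prox1, which marks granule cells of the dentate gyrus, and 480 and 129 of these nuclei came from the injected animals. The labels give no such tissue, and these groups were named from their leading genes after they were seen. The clusters led by Zbtb20 enter the excitatory sums. Excitatory nuclei without a subtype numbered 126 and 130 in the saline and 95 and 111 in the PTZ animals. Together these are fewer than 480, so part of the larger cluster carries a layer or claustrum name.

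A group of 1060 upper-layer nuclei was led by activity genes, Baz1a, Ptgs2, Grasp and Nptx2, although the activity lists had no part in the clustering. Genes outside the lists that changed with PTZ, such as Mir670hg, were not kept out of it. The split of this group by treatment is not given here. A cluster of 413 nuclei with excitatory markers was led by the myelin genes Mog, Mag and Mobp, with 265 nuclei from untreated and 148 from injected animals. A cluster of 125 nuclei was led by Hspa8, the tubulin genes Tubb2a and Tuba1a, and the globin gene Hbb-bs, and 123 of them were from untreated animals. The last 2 groups were left unnamed.

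Arc was lower in excitatory nuclei of the PTZ animals, while Fos, Fosb and Nptx2 were higher. Lower depth of the PTZ libraries does not account for the whole of it, since with each nucleus thinned to the same depth the share with an Arc UMI still differed by -2.30 percentage points (highest PTZ animal 1.39%, lowest saline animal 2.61%). A different mix of subtypes may add to it, but both PTZ animals lay below both saline animals in 4 of 6 excitatory subtypes, as in layer 6 (72.7 to 12.7 CPM), and not in upper-layer or layer 6b neurons. Arc raised by the injection in saline animals would leave PTZ animals within the untreated range, but saline was at 0.734 of the untreated mean and PTZ, at 10.4 and 18.8 CPM, lay below the untreated range of 28.4 to 111. The untreated libraries differ from the injected ones in tissue and depth, which limits that comparison, and a fall of nuclear Arc RNA 1 h after PTZ stays open as the biological hypothesis, with the call lost without saline replicate 1 (-0.93).

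Mir670hg was higher in excitatory, inhibitory and medium spiny neurons of the PTZ animals. RNA shed by medium spiny neurons, where it was highest, may reach other nuclei, but 11 markers of those neurons stood in excitatory nuclei at a median of 4.26% of their medium spiny level (upper quartile 4.88%), against 34.6% for Mir670hg. Reads of a neighbouring gene would bring a like change there, but of 6 genes tested within 200 kb, none of which overlaps it, the largest log2 fold change in excitatory neurons was 0.60, for Hsd17b12 (adjusted p = 0.0214), against 2.20 for Mir670hg. Of the 4 overlapping genes, all of them microRNA genes, 0 had counts to test, so reads from these cannot be told apart. An activity-induced transcript is the biological hypothesis, found and tested on the same 4 animals, and in inhibitory neurons the rise no longer passed without saline replicate 2 (1.61).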
